A study of Mus musculus with 25 samples.

How the data were processed

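Polyadenylated RNA of the mouse duodenum was sequenced in 25 libraries, which the labels place in 5 groups by genotype and diet. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic, aligned with HISAT2 to GRCm38, handled with SAMtools, counted per gene with featureCounts and tested with DESeq2; no versions are recorded there, and the strand setting, the gene annotation release and the treatment of reads that match several genes are not given in the sources used here. The deposited counts are whole numbers of reads per gene, not normalised. The deposited log2 fold changes and the deposited p-values adjusted for multiple testing are DESeq2 results of the authors, per the file headers, for the comparisons WT_Full vs WT_Con and KI_Half vs WT_Half. The deposited signal column is a mean over libraries of normalised counts, per the file headers, and a further deposited column gives a count of libraries per gene, which equalled the number of libraries above 20 counts for all 17007 genes. Its smallest value was 5, so genes seen in fewer libraries were not analysed here.

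The 2 deposited tables held the same counts for the 25 libraries, and the signal column differed between them by at most 4.70e-05. Each had 17220 lines for 17007 gene identifiers, and 213 repeats of an identifier under another name were merged, since their counts were equal. Of the identifiers, 16995 were found in the GENCODE M21 annotation of GRCm38, which gave positions and missing names, and 15403 had a symbol in the deposited tables. Library totals ran from 24.6 to 44.8 M (mega) counts, with a median of 32.0 M. No column of values per sample was left unused.

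Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each of 6 comparisons was fitted on its own 2 groups with the quasi-likelihood F test of edgeR, trimmed mean of M values (TMM) normalisation, the default filter on low counts by group, no covariate, and a two-sided Benjamini-Hochberg adjusted p under 0.05. Levels are counts per M counts of a library (CPM) after TMM over all libraries, as mean ± SD, and log2 fold changes are given ± standard error (SE). The p-values of single genes are judged against the spread between the libraries of a group. Of 50 gene lists of pathways, organelles and cell types, those with at least 3 genes tested were compared with all other genes by camera with a preset correlation of 0.01, again with camera and an estimated correlation, and by fry, which asks whether the genes of a list move, on balance, one way. Members of a list were counted with adjustment over all genes tested and adjusted over the list alone. The p-values of fry also rest on the spread between libraries. Camera with the preset correlation and Fisher's exact tests take genes as units, so their p-values are not evidence over animals.

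The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with an average log2 CPM of at least 1, leaving out antigen receptor segments and genes without a symbol of their own. Where no gene passed, it takes the 5 with the smallest p in each direction. It adds the 3 tested members with the smallest p of each list past camera, and of the lists for alcohol and aldehyde metabolism, antimicrobial and acute-phase genes, inflammatory cytokines, tight junctions, pancreatic acinar cells and smooth muscle whatever their p, and Aldh2. All genes of the first kind and members of a part of the lists are named. Which of the lists past camera are described was chosen after the results were seen.

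Alternatives chosen beforehand were DESeq2, limma-voom with sample quality weights, 1 edgeR fit of all 25 libraries, relative log expression size factors, no filter on low counts, a block for the replicate number, and leaving out each library in turn. The block kept only replicate numbers found in both groups. This left 4 pairs in WT_Half vs WT_Con and WT_Full vs WT_Half, 6 in KI_Half vs WT_Half and 3 in KI_Half vs KI_Con. Added after the data were seen were DESeq2 with all 25 libraries, a covariate for Brunner gland content (the mean log2 CPM of Muc6, Tff2 and Gkn3), leaving out control libraries above 10 CPM of the acinar gene Ctrb1, and fits of genotype with diet over 21 libraries. The steps were tested on simulated counts drawn from the means, dispersions and library sizes of each comparison, with every gene drawn independently. Of 100 genes changed 2-fold, edgeR recovered 20 in the design of WT_Full vs WT_Con (16882 genes), 78 in KI_Half vs WT_Half (16907), 43 in WT_Half vs WT_Con (16993), 44 in WT_Full vs WT_Half (16967), 66 in KI_Half vs KI_Con (16944) and 50 in KI_Con vs WT_Con (16813). Of 100 genes changed 4-fold it recovered 94 to 99, with 4 to 9 false calls, while DESeq2 made 38 to 50. Among these were 48 in the design of WT_Full vs WT_Half and 44 in that of KI_Con vs WT_Con. On the real counts DESeq2 called 20 and 11 genes there. Each simulation held both the 2-fold and the 4-fold changes, and false calls can grow with the number of true ones. The false calls therefore cannot be set directly against the 20 and 11. A list of 32 proliferation genes moved 1.5-fold passed camera in each design, as did 0 or 1 of the 49 unmoved lists. Genes of real lists can move together, with an estimated correlation of 0.924 for smooth muscle in WT_Full vs WT_Con. How often camera passes unmoved lists in the real data is therefore not shown by these simulations.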

Results

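The duodenum is the first part of the small intestine and meets swallowed ethanol early. RNA was sequenced from this tissue in male C57BL/6N mice, here called wild type (WT), and in mice with an Aldh2 knock-in (KI). Aldh2 encodes the mitochondrial enzyme that oxidises acetaldehyde, the first product of ethanol breakdown. Mice were 8 weeks old at the start and were fed for 8 weeks. The WT_Con and KI_Con groups received a control diet. The WT_Half and KI_Half groups received 2.5% ethanol in the diet with 2 g/kg ethanol by gavage 2 times a week, and the WT_Full group 5% ethanol with 4 g/kg by gavage 2 times a week. Tissue was taken 9 h after a last gavage, for which 5 g/kg is stated. Whether control mice were gavaged, and whether the WT_Half and KI_Half groups also received 5 g/kg last, is not given in the sources used here. An effect of gavage itself was therefore not separated from ethanol. A time of collection is given only for the ethanol groups, counted from the gavage. A difference in time of day, which matters for clock genes, was not separated either. There were 4 WT_Con, 4 KI_Con, 7 WT_Half, 6 KI_Half and 4 WT_Full libraries. Totals were 29.5 to 44.8 M counts in WT_Con, 27.3 to 32.7 M in KI_Con, 30.2 to 41.0 M in WT_Half, 27.6 to 34.6 M in KI_Half and 24.6 to 33.2 M in WT_Full.

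Aldh2 itself (ENSMUSG00000029455, GRCm38 chromosome 5, 121566027 to 121593824, minus strand) was counted in every group. Its level was 479 ± 21 CPM in WT_Con (n = 4), 440 ± 74.9 in WT_Half (n = 7), 449 ± 128 in WT_Full (n = 4), 441 ± 24.0 in KI_Con (n = 4) and 363 ± 54.8 in KI_Half (n = 6). No comparison of Aldh2 passed the threshold with edgeR. The log2 difference was -0.13 ± 0.09 for KI_Con vs WT_Con (adjusted p = 0.618), -0.28 ± 0.14 for KI_Half vs WT_Half (0.369) and -0.27 ± 0.12 for KI_Half vs KI_Con (0.0918). A knock-in that keeps the transcript need not change its level, so these counts neither check nor contradict the genotype labels. The lower value passed with limma-voom in KI_Half vs KI_Con (adjusted p = 0.0157) and in KI_Half vs WT_Half (0.0434), and with edgeR in KI_Half vs KI_Con without KI_Half replicate 7 (0.00732).

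WT_Full vs WT_Con asked what the stronger ethanol regimen did in wild-type mice. Atf5, a transcription factor of the mitochondrial stress response (ENSMUSG00000038539, chromosome 7, 44812256 to 44816658), rose from 29.0 ± 1.63 to 80.5 ± 7.21 CPM (n = 4 each), a log2 change of 1.48 ± 0.13 with adjusted p = 0.0108. Genes of T and NK cells lay lower in the WT_Full libraries. Ccl5, a T cell chemokine, had 1.80 ± 0.807 against 21.6 ± 8.02 CPM, Cd3g of the T cell receptor complex 1.17 ± 0.592 against 11.2 ± 4.5, and the T cell antigen Cd7 1.35 ± 0.653 against 10.2 ± 3.44. None of these passed over all genes (adjusted p = 0.0575, 0.0580 and 0.0601), while 18 of 18 genes of the list passed adjusted over the list alone. Camera placed the list below other genes (adjusted p = 2.44e-37; adjusted p = 0.294 with an estimated correlation), and it was the 1 list that passed with fry (adjusted p = 0.0352).

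MHC class II genes followed the same direction in WT_Full vs WT_Con, with all 11 genes at a negative fold change, 0 past the threshold over all genes and 7 lower adjusted over the list alone. H2-Aa stood at 50.7 ± 48.6 against 221 ± 30.6 CPM, H2-Eb1 at 64.8 ± 53.7 against 239 ± 24.4 and H2-DMb1 at 10.5 ± 9.36 against 47.9 ± 7.69. By camera the MHC class II list had adjusted p = 1.80e-08, and adjusted p = 0.890 with an estimated correlation. The mean log2 CPM of the list was 4.34 in WT_Full replicate 4, 1.87 to 2.98 in the other WT_Full libraries and 4.38 to 4.72 in WT_Con. Of 13 B and plasma cell genes 12 also had a negative fold change, with a median of -0.93 and 0 past either adjustment, adjusted over the list alone included (camera adjusted p = 0.000241, and adjusted p = 0.890 with an estimated correlation). Their mean log2 CPM was 3.87 and 4.08 in WT_Full replicates 3 and 4, within the 3.59 to 4.55 of WT_Con, and 2.10 and 2.27 in WT_Full replicates 1 and 2. Of 20 circadian clock genes, 0 passed over all genes and 1 was higher and 10 lower adjusted over the list alone. For these genes time of collection was not separated from ethanol. The clock repressors Nr1d1, with a log2 change of -1.36 ± 0.29, Per1, with -1.15 ± 0.24, and Ciart, with -2.06 ± 0.31, had adjusted p of 0.129, 0.129 and 0.0756. By camera the clock list had adjusted p = 0.000186, and adjusted p = 0.890 with an estimated correlation. Its mean log2 CPM was 4.98 in WT_Full replicate 4, within the 4.88 to 5.35 of WT_Con, and 4.10 to 4.55 in the other WT_Full libraries. Of 15 heat shock genes 0 passed over all genes and 6 were higher adjusted over the list alone, among them the mitochondrial chaperonins Hspd1, with 513 ± 188 against 237 ± 34.2 CPM, and Hspe1, with 243 ± 96.2 against 104 ± 12.4, and the cytosolic Hsp90aa1, with 470 ± 161 against 218 ± 39.1. By camera the heat shock list had adjusted p = 0.000112, and adjusted p = 0.890 with an estimated correlation. Its mean log2 CPM was 6.21 in WT_Full replicate 4, within the 5.96 to 6.53 of WT_Con, and 6.65 to 7.07 in the other WT_Full libraries.

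Antimicrobial genes of Paneth cells had higher values in WT_Full vs WT_Con, at low levels. Of 15 such genes, 0 passed over all genes, while 12 were higher and 2 lower adjusted over the list alone. The alpha-defensins Defa22, Defa21 and Defa17 had 3.27 ± 3.26, 3.24 ± 3.70 and 6.79 ± 5.30 CPM in WT_Full against 0.237 ± 0.0974, 0.204 ± 0.177 and 1.31 ± 0.534 in WT_Con. By camera the Paneth cell list had adjusted p = 3.20e-06, and adjusted p = 0.890 with an estimated correlation. Defensin genes are near-identical copies, so their counts may be shared between members. Among 17 antimicrobial and acute-phase genes 0 passed over all genes and 1 was higher adjusted over the list alone. Transcripts of the phospholipase gene Pla2g2a had 5.92 ± 4.56 against 0.891 ± 0.631 CPM, the siderophore-binding Lcn2 25.9 ± 24.0 against 5.64 ± 3.06, and the serum amyloid gene Saa3 7.99 ± 7.99 against 1.21 ± 1.18. By camera the antimicrobial list had adjusted p = 0.0261, and adjusted p = 0.890 with an estimated correlation. That list missed the threshold without WT_Con replicate 1, 2 or 3 or WT_Full replicate 2, 3 or 4, with adjusted p from 0.0549 to 0.316.

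Of 18 genes of iron, calcium and zinc handling in WT_Full vs WT_Con, 0 passed over all genes and 2 were lower adjusted over the list alone. The ferric reductase Cybrd1 had 232 ± 131 against 644 ± 201 CPM, and the iron exporter Slc40a1 505 ± 273 against 1241 ± 293, and the transcription factor Epas1 125 ± 57.0 against 230 ± 40.5. By camera the metal handling list had adjusted p = 0.0154, and adjusted p = 0.890 with an estimated correlation. The list missed the threshold without WT_Con replicate 1 (adjusted p = 0.0654) or WT_Full replicate 3 (0.114). Its mean log2 CPM was 7.77 in WT_Full replicate 4, within the 7.52 to 7.88 of WT_Con, and 6.39 to 7.18 in the other WT_Full libraries. Of 23 genes of alcohol and aldehyde metabolism, 20 had a negative fold change and 0 passed by either adjustment, adjusted over the list alone included. Aldh6a1 of valine breakdown had a log2 change of -0.80 ± 0.21, the proline-degrading Aldh4a1 -1.30 ± 0.56 and the acetate-activating Acss2 -0.46 ± 0.17. By camera the alcohol and aldehyde list had adjusted p = 0.00636, and adjusted p = 0.890 with an estimated correlation, or 0.0505 without WT_Con replicate 2 and 0.0550 without WT_Full replicate 3. Here too WT_Full replicate 4, with a mean log2 CPM of 6.44, lay within the 6.05 to 6.49 of WT_Con, and the other WT_Full libraries at 5.17 to 5.71. Inflammatory cytokines (0 of 23 past over all genes, 1 lower adjusted over the list alone, camera adjusted p = 0.918), tight junctions (0 of 24, 1 lower adjusted over the list alone, 0.627) and smooth muscle (0 of 14, 0 adjusted over the list alone, 0.118) did not pass. Il18 stood at 129 ± 19.1 against 89.3 ± 18.0 CPM, Icam1 at 5.30 ± 2.44 against 10.1 ± 1.25. Cldn1 stood at 0.447 ± 0.219 against 3.57 ± 2.35, Tjp3 at 306 ± 47.0 against 221 ± 33.3, Cldn3 at 368 ± 44.1 against 269 ± 40.8. Among smooth muscle genes Pcp4 stood at 1.26 ± 1.26 against 0.360 ± 0.252, Hspb6 at 45.8 ± 24.6 against 27.5 ± 9.78 and Actg2 at 338 ± 177 against 219 ± 57.1.

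Digestive enzymes of the exocrine pancreas separated some control libraries from all others. In WT_Full vs WT_Con, 0 of 21 acinar genes passed over all genes, and 1 was higher and 17 lower adjusted over the list alone. The procarboxypeptidase Cpb1 had 0.486 ± 0.194 against 88.2 ± 93.6 CPM, the elastase Cela2a 0.462 ± 0.199 against 151 ± 165 and the lipase-related Pnliprp1 0.676 ± 0.398 against 42.6 ± 43.5. By camera the acinar list had adjusted p = 8.00e-12, and adjusted p = 0.890 with an estimated correlation. The summed level of 15 acinar genes was 2579, 10.9, 1990 and 239 CPM in WT_Con replicates 1 to 4. In KI_Con replicates 1 to 4 it was 5252, 1772, 18.2 and 16.9 CPM, and in the 17 libraries from ethanol-fed mice at most 50.2 CPM. These 15 genes were chosen for a low level in every ethanol library and a higher one in some control library. Muc6, a mucin of Brunner glands, ran from 6.73 to 2631 CPM in WT_Full and from 11.9 to 21350 CPM in WT_Con.

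**Figure D1:**
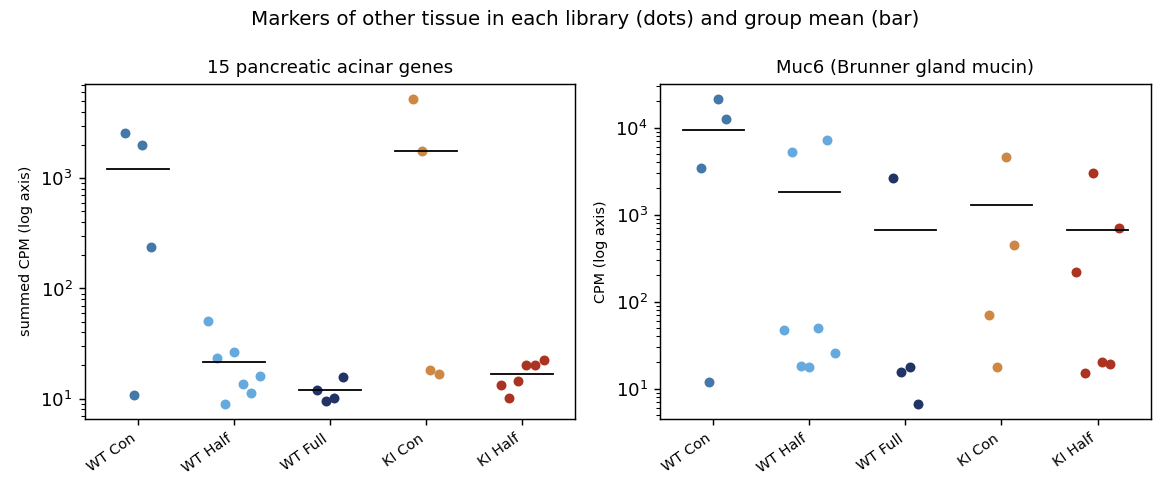
Summed CPM of 15 pancreatic acinar genes (left) and CPM of Muc6, a Brunner gland mucin (right), on log axes, for each of the 25 libraries (dots) with the group mean (bar). The acinar sum was 239 CPM or more in 5 of 8 control libraries and stayed at or below 50.2 CPM in the 17 ethanol libraries. Its 15 genes were chosen for a low level in every ethanol library and a higher one in some control library. Muc6 varied within each group.

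In total, edgeR found 1 gene higher and 0 lower among 16882 tested in WT_Full vs WT_Con, where 3003 genes had an unadjusted p under 0.05. Camera passed 15 of 50 lists and 0 with an estimated correlation. DESeq2 on the same libraries found 505 higher and 431 lower, limma-voom 811 higher and 599 lower and the fit of all 25 libraries 683 higher and 606 lower, while the authors' deposited table held 988 higher and 964 lower genes at an adjusted p under 0.05. The count depended on single libraries: it was 2069 without WT_Full replicate 4, 12 without WT_Con replicate 2, and 0 without WT_Con replicate 1, 3 or 4 or WT_Full replicate 1 or 3. It was 0 with the Brunner gland covariate, with the replicate block and without control libraries above 10 CPM of Ctrb1, which leaves 1 WT_Con library, so that a loss of calls there is no evidence against them. In these fits, in this order, Atf5 had an adjusted p of 0.0748, 0.136 and 0.845 at a log2 change of 1.55, 1.48 and 1.49.

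**Figure D2:**
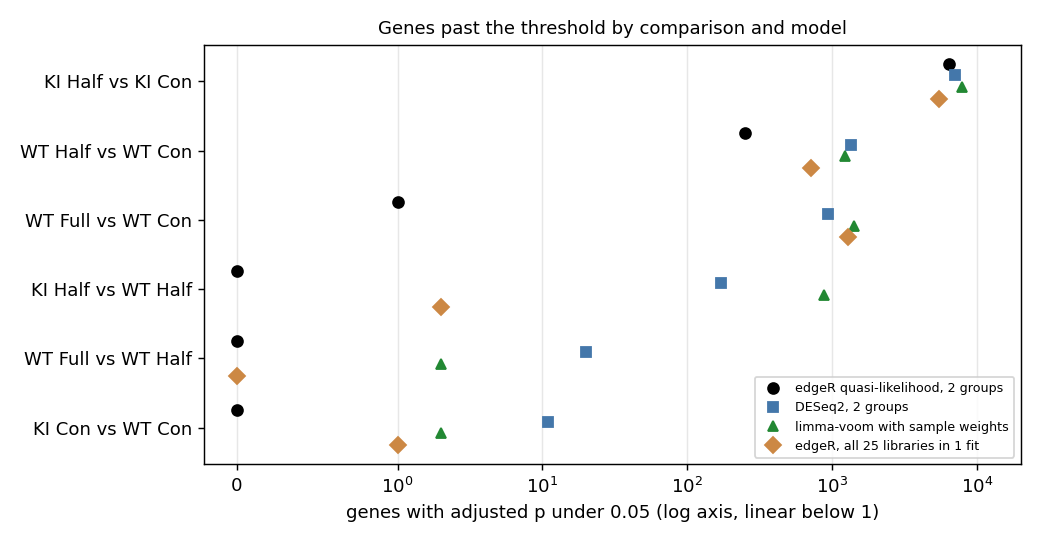
Number of genes with an adjusted p under 0.05 (horizontal, log axis that is linear below 1) in each of the 6 comparisons (vertical) under 4 models, each with its own symbol. KI_Half vs KI_Con gave 5439 to 7888 genes under the 4 models, while WT_Full vs WT_Con ranged from 1 to 1410.

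KI_Half vs WT_Half compared the genotypes under the milder ethanol regimen, and edgeR called 0 of 16907 genes. The gene with the smallest p was Tmem116 (ENSMUSG00000029452, chromosome 5, 121451893 to 121524183), a neighbour of Aldh2, with 10.5 ± 2.38 CPM in KI_Half (n = 6) against 3.66 ± 1.29 in WT_Half (n = 7), a log2 difference of 1.52 ± 0.23 and an adjusted p of 0.126. The next on the higher side were the chemokine Ccl20, at 93.9 ± 86.9 against 3.55 ± 2.03 CPM, Samd10, the transcription factor Cebpb, at 15.6 ± 4.54 against 7.24 ± 2.00, and Tpm3-rs7, each with adjusted p = 0.254. On the lower side were Chodl (log2 difference -1.07 ± 0.22), the guanylate cyclase subunit Gucy1a1 (-0.85 ± 0.18), the cytochrome Cyp4f40 (-0.86 ± 0.19), the matrix protein Thbs2 (-0.89 ± 0.20) and the collagen Col6a3 (-0.78 ± 0.17), with adjusted p from 0.254 to 0.265.

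Several lists of stress and inflammation genes had higher mean values in KI_Half vs WT_Half, carried for several genes by KI_Half replicates 1, 2, 3 and 5. Nos2 had 4.95 to 89.1 CPM in these, 0.553 and 2.18 in replicates 6 and 7, and 0.533 to 4.33 in WT_Half. Il33 had 149 to 684 CPM in these, 67.5 and 19.3 in replicates 6 and 7, and 22.4 to 118 in WT_Half. Of 20 genes of the integrated stress response, 19 had a positive fold change, 0 passed over all genes and 10 were higher adjusted over the list alone. Atf4, its main transcription factor, had 387 ± 81.7 against 261 ± 25 CPM and the stress hormone Gdf15 7.81 ± 2.65 against 2.91 ± 1.31. By camera the integrated stress list had adjusted p = 1.22e-13, and adjusted p = 0.199 with an estimated correlation. Of 24 inflammatory cytokine genes, 0 passed over all genes and 10 were higher adjusted over the list alone. The alarmin Il33 stood at 307 ± 268 against 50.8 ± 32.1 CPM and the neutrophil chemokine Cxcl1 at 10.9 ± 6.92 against 2.82 ± 1.94. By camera the inflammatory cytokine list had adjusted p = 7.54e-06, and adjusted p = 0.512 with an estimated correlation. Of 17 antimicrobial and acute-phase genes, 0 passed over all genes and 4 were higher adjusted over the list alone. Lcn2 had 350 ± 403 against 28.6 ± 19.6 CPM, the nitric oxide synthase Nos2 31.6 ± 35.6 against 1.51 ± 1.34, and Duoxa2, a partner of an epithelial hydrogen peroxide source, 106 ± 141 against 3.99 ± 5.51. By camera the antimicrobial list had adjusted p = 0.000352, and adjusted p = 0.512 with an estimated correlation. Of 29 genes of the oxidative stress response to NRF2, 0 passed over all genes and 3 were higher adjusted over the list alone. The cystine carrier Slc7a11 had a log2 difference of 2.00 ± 0.45, the heme oxygenase Hmox1 1.72 ± 0.39 and the reductase Akr1b8 1.45 ± 0.36. By camera the NRF2 list had adjusted p = 0.000971, and adjusted p = 0.603 with an estimated correlation. Of 18 glucocorticoid-responsive genes 15 and of 26 immediate early genes 24 had a positive fold change, with 0 past over all genes and 1 each higher adjusted over the list alone. Camera gave adjusted p = 1.00e-05 and 7.54e-06, and adjusted p = 0.603 and 0.730 with an estimated correlation. Not all stress lists moved this way. A negative fold change was found for 17 of 22 endoplasmic reticulum chaperone and 10 of 15 heat shock genes. Neither list passed camera (adjusted p = 0.229 and 0.409), with 0 genes past either adjustment, adjusted over the list alone included. Of 23 hypoxia and glycolysis genes 11 had a positive and 12 a negative fold change. 0 passed over all genes and 4 were higher adjusted over the list alone (camera adjusted p = 0.229). Of 17 enteroendocrine genes, 0 passed over all genes and 5 were higher adjusted over the list alone. Cck had 46.1 ± 4.78 against 32.7 ± 5.70 CPM, Chgb 222 ± 24.2 against 144 ± 39.3 and Pax6 1.82 ± 0.389 against 1.09 ± 0.226. By camera the enteroendocrine list had adjusted p = 4.16e-07, and adjusted p = 0.199 with an estimated correlation. Of 8 ileum marker genes Fabp6, Fgf15 and Nts were not in the data. Gcg and Pyy of the 5 left are also on the enteroendocrine list, so the lists are not independent. Of these 5 ileum marker genes 4 had a positive fold change, 0 passed over all genes and 1 was higher adjusted over the list alone. By camera the ileum list had adjusted p = 0.00437, and adjusted p = 0.199 with an estimated correlation. Its mean log2 CPM was 4.05 to 4.82 in KI_Half and 3.35 to 4.06 in WT_Half.

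Other groups had lower values in KI_Half vs WT_Half. Of 37 interferon-stimulated genes 35 had a negative fold change, with Stat2 at 53.7 ± 15.9 against 86.3 ± 27.8 CPM, Ifit2 at 5.85 ± 2.19 against 11.8 ± 6.31 and Herc6 at 5.72 ± 2.23 against 13 ± 8.45. 0 passed over all genes and 0 adjusted over the list alone. By camera the interferon list had adjusted p = 5.75e-11, and adjusted p = 0.603 with an estimated correlation. Of 29 genes of brush border digestion and nutrient uptake 26 had a negative fold change, 0 passed over all genes and 1 was lower adjusted over the list alone. The aminopeptidase Anpep had 312 ± 109 against 609 ± 142 CPM, Enpep 80.8 ± 27.3 against 142 ± 38.8 and the protease Mep1b 209 ± 79.6 against 331 ± 96.5. By camera the brush border list had adjusted p = 0.000362, and adjusted p = 0.800 with an estimated correlation. Of 15 fibroblast genes 14 had a negative fold change, 0 passed over all genes and 2 were lower adjusted over the list alone. Log2 differences were -0.51 ± 0.16 for Col1a1, -0.70 ± 0.22 for Col3a1 and -0.57 ± 0.21 for Col1a2. By camera the fibroblast list had adjusted p = 0.000189, and adjusted p = 0.603 with an estimated correlation. All 18 T and NK cell genes and 11 of 12 B and plasma cell genes had a negative fold change, with 0 past either adjustment, adjusted over the list alone included. Camera gave adjusted p = 0.00437 and 0.0471, and adjusted p = 0.799 with an estimated correlation for both. The T and NK cell list missed the threshold without WT_Half replicate 6 (0.0715), and the B and plasma cell list without KI_Half replicate 2 or WT_Half replicate 2 or 6 (0.136 to 0.183). All 5 gastric marker genes had a negative fold change, 0 passed over all genes and 2 were lower adjusted over the list alone. By camera the gastric list had adjusted p = 0.0249, and adjusted p = 0.603 with an estimated correlation. Of 23 genes of alcohol and aldehyde metabolism 22 had a negative fold change and 0 passed by either adjustment, adjusted over the list alone included. Aldh6a1 stood at 17.7 ± 2.23 against 23.2 ± 4.55 CPM, Aldh1b1 at 215 ± 70.7 against 284 ± 61.8 and Adh7 at 0.935 ± 0.433 against 1.66 ± 0.783. By camera the alcohol and aldehyde list had adjusted p = 0.00389, and adjusted p = 0.736 with an estimated correlation. Tight junction, smooth muscle and acinar genes did not pass camera (0.0799, 0.418 and 0.461) and had 0 members past either adjustment, adjusted over the list alone included. Values were 722 ± 84.4 against 594 ± 24.1 CPM for Cldn7, 35.4 ± 12.8 against 24.0 ± 4.2 for Cldn23, 45.2 ± 14.6 against 32.5 ± 3.23 for Cldn12. They were 39.9 ± 7.31 against 50.4 ± 14.7 for Lmod1, 57.1 ± 5.85 against 66.1 ± 11.3 for Smtn, 1.21 ± 0.381 against 1.70 ± 0.541 for Tagln, and 1.46 ± 0.660 against 2.45 ± 1.21 for Ctrl, 0.954 ± 0.338 against 2.57 ± 4.05 for Pnlip and 0.804 ± 0.462 against 1.63 ± 1.86 for Cpa1.

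In KI_Half vs WT_Half the unadjusted p was under 0.05 for 2398 genes, and camera passed 16 of 50 lists, 0 with an estimated correlation. DESeq2 on these 13 libraries called 121 genes higher and 51 lower, limma-voom 379 higher and 505 lower, the fit of all 25 libraries 2, and the authors' deposited results held 153 higher and 58 lower. Without WT_Half replicate 2, edgeR called 1 gene, Tmem116 (adjusted p = 0.0108).

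The deposited comparisons WT_Full vs WT_Con and KI_Half vs WT_Half share no library. With edgeR 0 genes were called in both, from 1 and 0 calls. With DESeq2, 22 genes were higher in both where 3.59 would be shared by independent lists (odds ratio 7.55, two-sided Fisher's exact p = 8.03e-12 across genes), and 1 was lower in both where 1.29 would be (p = 1). Of the 505 genes called higher by DESeq2 in WT_Full vs WT_Con, the 502 tested in KI_Half vs WT_Half had a median log2 difference of 0.19 there (camera p = 1.90e-15, and p = 0.124 with an estimated correlation). Of the 431 called lower, the 423 tested there had -0.28 (camera p = 2.52e-06, and p = 0.356 with an estimated correlation). Across 16793 genes, which are not independent, the fold changes correlated with r = 0.324.

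WT_Half vs WT_Con gave the effect of the milder regimen in wild-type mice, with 152 genes higher and 97 lower among 16993. S100a9, a calcium-binding protein of neutrophils, went from 0.145 ± 0.0636 to 4.28 ± 3.08 CPM (log2 change 4.83 ± 0.69, adjusted p = 0.0135), the neutrophil chemokine Cxcl2 from 0.0898 ± 0.0876 to 3.60 ± 3.84 (5.32 ± 1.14, 0.0420) and Saa3 from 1.21 ± 1.18 to 16.3 ± 6.18 (3.78 ± 0.57, 0.0145), for n = 4 and 7. The metalloproteinase Mmp3 rose from 0.228 ± 0.152 to 9.42 ± 4.32 CPM (5.31 ± 0.59, 0.00469). The related genes Ly6g, Gml and Gml2 of the Ly6 family rose by 6.83 ± 1.01, 3.81 ± 0.42 and 3.48 ± 0.36 on the log2 scale, with adjusted p of 0.0135, 0.00469 and 0.00469. Reads may be shared between family members. The keratin Krt84 was close to 0 in WT_Con (0 to 0.0302 CPM) and had 0.631 to 12 CPM in WT_Half (adjusted p = 0.0189).

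**Figure D3:**
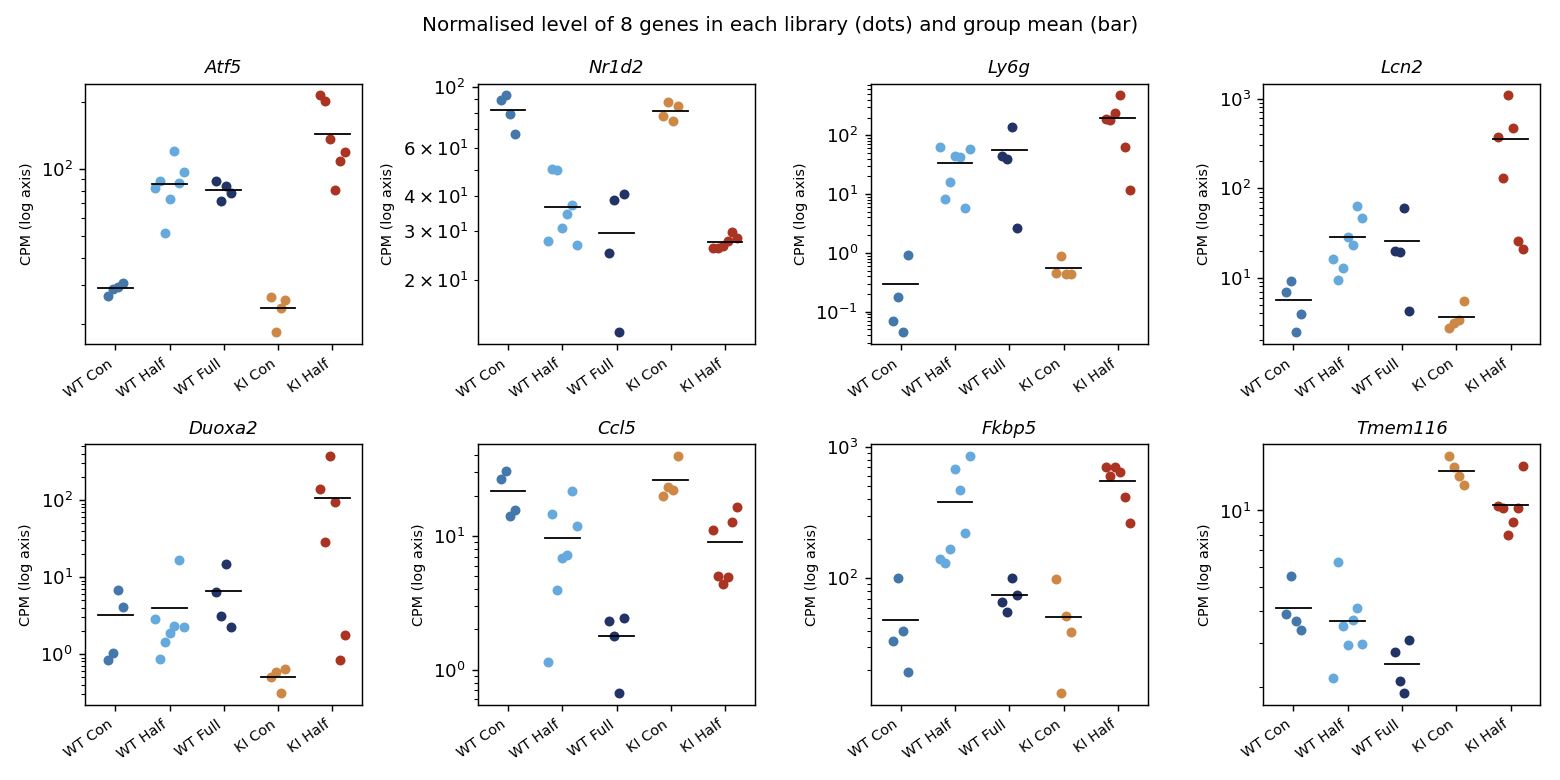
CPM (log axis) of Atf5, Nr1d2, Ly6g, Lcn2, Duoxa2, Ccl5, Fkbp5 and Tmem116 in each of the 25 libraries (dots) with the group mean (bar). Fkbp5 lay at 132 to 847 CPM in WT_Half and 55.9 to 101 in WT_Full, and Tmem116 at 8.01 to 16.4 CPM in KI and 1.90 to 6.24 in WT libraries.

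Of 20 genes of the integrated stress response in WT_Half vs WT_Con 3 passed over all genes, all higher, and 5 were higher adjusted over the list alone. These were the serine synthesis enzymes Psat1 (log2 change 2.40 ± 0.38, adjusted p = 0.0178) and Phgdh (1.67 ± 0.36, 0.0443) and the mitochondrial Shmt2 (1.27 ± 0.28, 0.0454). Camera gave adjusted p = 0.00122, and adjusted p = 0.949 with an estimated correlation. Of 18 glucocorticoid-responsive genes 1 passed over all genes and 8 were higher adjusted over the list alone. Fkbp5, a chaperone of the glucocorticoid receptor, rose from 48.2 ± 36.0 to 379 ± 290 CPM (adjusted p = 0.0497), while Hif3a had 3.57 ± 3.18 against 0.524 ± 0.257. By camera the glucocorticoid list had adjusted p = 0.000180, and adjusted p = 0.959 with an estimated correlation. Of 11 MHC class II genes 4 passed over all genes, all lower, and 7 were lower adjusted over the list alone. H2-Aa had a log2 change of -1.49 ± 0.30, H2-Eb1 of -1.33 ± 0.27 and H2-DMb1 of -1.93 ± 0.37 (adjusted p = 0.0369, 0.0369 and 0.0279). By camera the MHC class II list had adjusted p = 2.58e-09, and adjusted p = 0.949 with an estimated correlation. Of 13 B and plasma cell genes 11 had a negative fold change, with a median of -0.63 and 0 past either adjustment, adjusted over the list alone included (camera adjusted p = 0.00428, adjusted p = 0.959 with an estimated correlation, and 0.0555 and 0.0508 without WT_Con replicate 2 or 4). Of 18 T and NK cell genes 0 passed over all genes and 9 were lower adjusted over the list alone. The integrin Itgae stood at 6.37 ± 3.00 against 16.6 ± 6.49 CPM, Cd3g at 3.67 ± 2.32 against 11.2 ± 4.5 and Trac at 2.10 ± 1.21 against 5.04 ± 1.02. By camera the T and NK cell list had adjusted p = 5.44e-10, and adjusted p = 0.949 with an estimated correlation. Among 18 antimicrobial and acute-phase genes 1, Saa3, passed over all genes and 4 were higher adjusted over the list alone. Lcn2 stood at 28.6 ± 19.6 against 5.64 ± 3.06 CPM and Ifitm3 at 69.0 ± 14.6 against 45.1 ± 11.7. By camera the antimicrobial list had adjusted p = 0.00751, and adjusted p = 0.949 with an estimated correlation.

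The largest falls in WT_Half vs WT_Con were of acinar genes and Cldn18, a claudin of the stomach. Of 22 acinar genes, 1 was higher and 15 lower over all genes, and 1 higher and 18 lower adjusted over the list alone. The control means rest on the same WT_Con libraries that held pancreatic transcripts. Cpb1 had 0.850 ± 0.567 against 88.2 ± 93.6 CPM, Cel 1.36 ± 1.23 against 135 ± 151, Prss2 1.46 ± 1.16 against 129 ± 139, Cela3b 0.820 ± 0.724 against 69.7 ± 71.9, Cela2a 1.83 ± 1.62 against 151 ± 165, Ctrb1 2.86 ± 2.86 against 234 ± 242, Try5 0.489 ± 0.506 against 39.2 ± 40.0 and Pnliprp1 1.87 ± 0.575 against 42.6 ± 43.5 (adjusted p from 0.0172 to 0.0256). By camera the acinar list had adjusted p = 1.09e-13, and adjusted p = 0.949 with an estimated correlation. Trypsin genes such as Prss2 and Try5 are near-identical copies. Cldn18 had 0.415 ± 0.266 against 110 ± 219 CPM (adjusted p = 0.0451), a control mean carried by WT_Con replicate 3 at 439 CPM, with at most 1.41 CPM in every other library. Gastric marker genes made up 1.53% of the counts of that library and at most 0.0549% elsewhere. Inflammatory cytokines did not pass camera (adjusted p = 0.187), although 3 of 24 rose over all genes, namely Il18 by 0.92 ± 0.16 (adjusted p = 0.0189), Cxcl1 by 2.18 ± 0.49 (0.0497) and Cxcl2, and 4 were higher and 1 lower adjusted over the list alone. For alcohol and aldehyde metabolism (0 of 23 over all genes, 0 adjusted over the list alone, camera 0.0742), tight junctions (1 of 25 over all genes and 2 adjusted over the list alone, lower, 0.785) and smooth muscle (0 of 14, 0 adjusted over the list alone, 0.494), the members with the smallest p had 109 ± 35.8 against 185 ± 26.8 CPM for Acss1, 27.3 ± 3.20 against 36.8 ± 6.08 for Acss2, 1.66 ± 0.783 against 5.08 ± 5.84 for Adh7, 0.812 ± 0.476 against 3.57 ± 2.35 for Cldn1, 1443 ± 181 against 1096 ± 195 for Cdh17, 66.1 ± 11.3 against 88.7 ± 18.0 for Smtn, 0.734 ± 0.334 against 0.360 ± 0.252 for Pcp4 and 51.3 ± 16.1 against 71.0 ± 16.3 for Synpo2.

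The count of WT_Half vs WT_Con was 1353 with DESeq2, 1232 with limma-voom and 720 in the fit of all 25 libraries, but 7 with the Brunner gland covariate. Leaving out control libraries above 10 CPM of Ctrb1 leaves 1 WT_Con library, so no count is given for it. With the replicate block, which also left out WT_Half libraries whose number WT_Con lacks, the count was 0. The block and the smaller number of libraries cannot be told apart in this count. Single libraries moved it from 249 to 21 without WT_Con replicate 1, 59 without WT_Con replicate 4, 122, 60, 57 and 72 without WT_Half replicates 3, 4, 5 and 7, and up to 375 and 446 without WT_Half replicates 1 and 6. 11 of 50 lists passed camera, 7 without WT_Half replicate 1, and 0 with an estimated correlation.

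KI_Half vs KI_Con gave the same regimen in knock-in mice and showed by far the most calls, 3388 genes higher and 3032 lower among 16944. Epithelial defence genes rose: Lcn2 from 3.68 ± 1.21 to 350 ± 403 CPM (log2 change 6.58 ± 1.21, adjusted p = 0.00215), the hydrogen peroxide source Duox2 from 1.64 ± 0.480 to 199 ± 256 (6.92 ± 1.49, 0.00461) and its partner Duoxa2 from 0.509 ± 0.142 to 106 ± 141 (7.71 ± 1.74, 0.00574), for n = 4 and 6. Ly6g rose from 0.555 ± 0.222 to 193 ± 162 CPM (8.43 ± 1.06, 0.000456) and the serine protease Prss22 from 0.145 ± 0.0878 to 25.9 ± 27.0 (7.48 ± 1.38, 0.00218). Csf3, a growth factor of neutrophils, the small proline-rich gene Sprr2f and Krt84 were close to 0 in KI_Con, at up to 0.0624, 0.0657 and 0.0985 CPM, and had 0.546 to 9.14, 0.619 to 11.6 and 0.800 to 14.6 CPM in KI_Half (adjusted p = 0.00106, 0.00110 and 0.00129). Of 19 antimicrobial and acute-phase genes 10 rose and 1 fell, by both adjustments, adjusted over the list alone included. Saa3 rose by 4.98 ± 0.41 and Lypd8, which keeps bacteria from the epithelium, by 1.05 ± 0.12. By camera the antimicrobial list had adjusted p = 0.000195, and adjusted p = 0.485 with an estimated correlation.

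Stress lists did not all move one way in KI_Half vs KI_Con. Of 29 NRF2 genes 7 rose and 8 fell, with 9 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.777), and of 22 endoplasmic reticulum chaperone genes 3 rose and 4 fell, with 4 higher and 5 lower adjusted over the list alone (0.652). Of 20 integrated stress response genes 13 rose and 0 fell, and 13 were higher and 1 lower adjusted over the list alone. The asparagine synthetase Asns rose by 2.66 ± 0.20, Phgdh by 2.53 ± 0.19 and Psat1 by 3.15 ± 0.24 on the log2 scale, each with adjusted p = 8.73e-05. By camera the integrated stress list had adjusted p = 1.16e-11, and adjusted p = 0.485 with an estimated correlation. Of 32 proliferation genes 29 rose, by both adjustments, adjusted over the list alone included. The ribonucleotide reductase Rrm2 rose by 3.31 ± 0.42, the mitotic kinase Cdk1 by 1.22 ± 0.16 and the replication factor Mcm3 by 1.05 ± 0.14. By camera the proliferation list had adjusted p = 1.32e-12, and adjusted p = 0.485 with an estimated correlation. Of 18 glucocorticoid-responsive genes 11 rose and 1 fell, by both adjustments, adjusted over the list alone included. Fkbp5 went from 50.6 ± 35.5 to 552 ± 178 CPM, Ddit4 from 24.5 ± 3.20 to 113 ± 34.4 and Hif3a from 0.545 ± 0.230 to 4.30 ± 1.97. By camera the glucocorticoid list had adjusted p = 7.86e-05, and adjusted p = 0.659 with an estimated correlation. Of 24 inflammatory cytokine genes 12 rose and 3 fell, and 13 were higher and 5 lower adjusted over the list alone. Log2 changes were 3.69 ± 0.61 for Cxcl1, 5.83 ± 0.99 for Cxcl2 and 3.94 ± 0.71 for Cxcl5, while the list did not pass camera (adjusted p = 0.1). Of 24 tight junction genes 5 rose and 2 fell, and 2 were higher and 2 lower adjusted over the list alone. The pore-forming Cldn2 rose from 113 ± 25.5 to 476 ± 142 CPM and the cadherin Cdh1 from 602 ± 28.7 to 1073 ± 289, and Cldn15 fell from 681 ± 72.0 to 198 ± 118 (camera adjusted p = 0.337).

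Most genes of the brush border and xenobiotic lists fell in KI_Half vs KI_Con, as did 10 of 23 of alcohol and aldehyde metabolism. The mean log2 CPM of lipid absorption genes overlapped, at 7.45 to 8.17 in KI_Half and 8.10 to 8.57 in KI_Con. Of 29 brush border and nutrient uptake genes 24 fell and 0 rose, and 1 was higher and 25 lower adjusted over the list alone. The peptide carrier Slc15a1 fell from 199 ± 15.3 to 72.6 ± 20.4 CPM, the fructose carrier Slc2a5 from 543 ± 108 to 151 ± 56.4 and the amino acid carrier Slc7a9 from 216 ± 22.0 to 139 ± 17.1. By camera the brush border list had adjusted p = 5.80e-10, and adjusted p = 0.485 with an estimated correlation. Marker genes of enterocytes moved the same way: of 18, 11 fell and 0 rose, 1 was higher and 11 lower adjusted over the list alone, and the median log2 change was -0.57. By camera the enterocyte list had adjusted p = 0.00111, and adjusted p = 0.694 with an estimated correlation. Of 49 genes of xenobiotic metabolism 3 rose and 32 fell, and 3 were higher and 33 lower adjusted over the list alone. Log2 changes were -2.23 ± 0.18 for Ugt2b5, -2.45 ± 0.30 for Ces2b and -0.85 ± 0.10 for Gsta4. By camera the xenobiotic list had adjusted p = 1.16e-11, and adjusted p = 0.485 with an estimated correlation. Of 23 genes of alcohol and aldehyde metabolism 10 fell and 0 rose, by both adjustments, adjusted over the list alone included. Log2 changes were -1.12 ± 0.15 for the catalase Cat, -1.83 ± 0.25 for Aldh4a1 and -0.91 ± 0.14 for Aldh3b1. By camera the alcohol and aldehyde list had adjusted p = 3.68e-05, and adjusted p = 0.485 with an estimated correlation. Of 18 genes of iron, calcium and zinc handling 2 rose and 11 fell, and 2 were higher and 13 lower adjusted over the list alone. The calcium carrier S100g fell from 1049 ± 226 to 228 ± 75.0 CPM, Slc40a1 from 1360 ± 106 to 457 ± 142 and the ferritin Fth1 from 15953 ± 1308 to 8899 ± 1388. By camera the metal handling list had adjusted p = 0.000323, and adjusted p = 0.485 with an estimated correlation. Of 20 clock genes 5 rose and 9 fell, by both adjustments, adjusted over the list alone included. Here too time of collection was not separated from ethanol. Nr1d2 had the smallest adjusted p of all genes (4.79e-06), from 81.5 ± 5.99 to 27.3 ± 1.43 CPM, with Dbp from 154 ± 13.6 to 21.1 ± 7.34 and Nr1d1 from 177 ± 54.1 to 39.0 ± 6.92. By camera the clock list had adjusted p = 0.000626, and adjusted p = 0.169 with an estimated correlation.

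**Figure D4:**
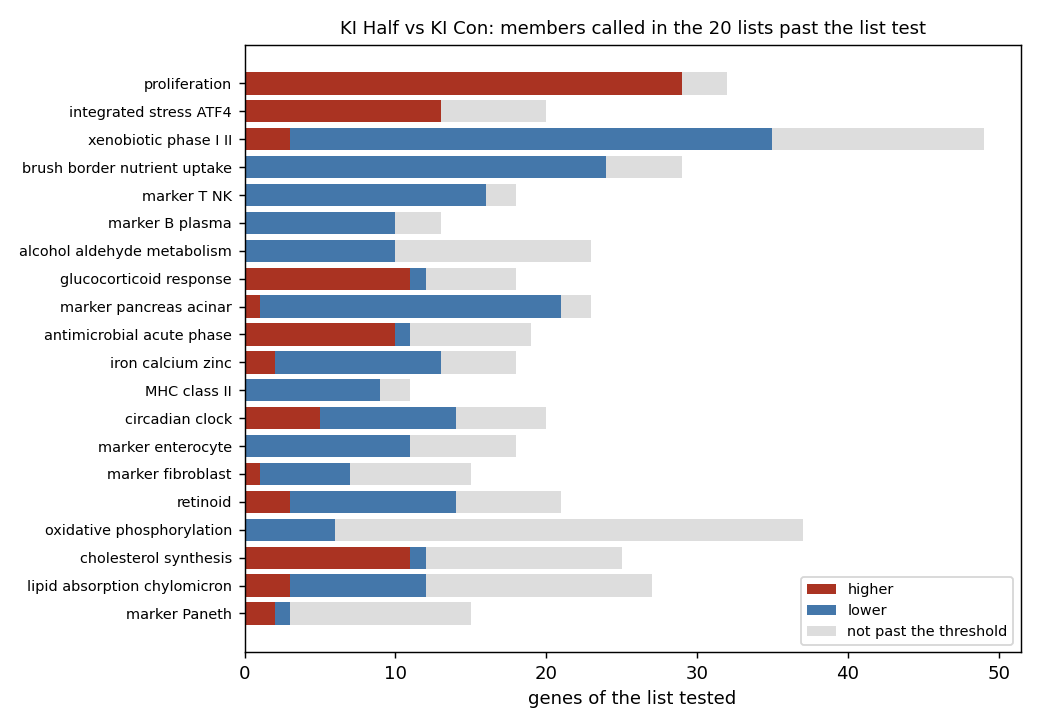
Number of genes (horizontal) higher, lower or not past an adjusted p of 0.05 over all genes in KI_Half vs KI_Con, for each of the 20 lists past camera (vertical, smallest camera p on top). Proliferation had 29 of 32 genes higher, and brush border and nutrient uptake 24 of 29 lower.

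Of immune cell genes in KI_Half vs KI_Con, those of T, NK, B and plasma cells and MHC class II mostly fell, while of 19 myeloid genes 5 rose and 6 fell, with 6 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.644). Of 18 T and NK cell genes 16 fell, by both adjustments, adjusted over the list alone included. Trbc1 went from 3.18 ± 0.408 to 1.06 ± 0.229 CPM, Trac from 4.04 ± 1.45 to 0.723 ± 0.642 and Itgae from 16.7 ± 4.71 to 4.04 ± 2.66. By camera the T and NK cell list had adjusted p = 2.71e-08, and adjusted p = 0.485 with an estimated correlation. Of 13 B and plasma cell genes 10 fell, and 11 were lower adjusted over the list alone. The antibody joining chain Jchain went from 1078 ± 171 to 359 ± 191 CPM, Cd79a from 16.0 ± 1.78 to 5.72 ± 2.82 and Mzb1 from 2.35 ± 0.553 to 0.620 ± 0.373. By camera the B and plasma cell list had adjusted p = 1.75e-05, and adjusted p = 0.541 with an estimated correlation. Of 11 MHC class II genes 9 fell, and 11 were lower adjusted over the list alone. Log2 changes were -2.17 ± 0.40 for H2-Ob, -1.55 ± 0.35 for H2-DMb2 and -1.39 ± 0.38 for H2-Oa. By camera the MHC class II list had adjusted p = 0.000336, and adjusted p = 0.694 with an estimated correlation. Of 14 smooth muscle genes 4 fell, by both adjustments, adjusted over the list alone included. Smtn had a log2 change of -0.85 ± 0.11, Synpo2 of -0.93 ± 0.23 and Lmod1 of -0.53 ± 0.15 (camera adjusted p = 0.123). Of 23 acinar genes 1 rose and 20 fell, by both adjustments, adjusted over the list alone included, against KI_Con libraries of which 2 held pancreatic transcripts. Cel had 0.915 ± 0.609 against 205 ± 280 CPM, Pnlip 0.954 ± 0.338 against 210 ± 284, Cela3b 0.535 ± 0.242 against 114 ± 167, Prss2 1.06 ± 0.285 against 210 ± 299. Cpa1 had 0.804 ± 0.462 against 151 ± 208, Cpb1 0.669 ± 0.244 against 123 ± 169, Cela2a 1.24 ± 0.291 against 219 ± 303 and Try4 0.575 ± 0.277 against 90.0 ± 129, with adjusted p from 0.00238 to 0.00328. By camera the acinar list had adjusted p = 0.000128, and adjusted p = 0.735 with an estimated correlation. Spink1 had a log2 change of -1.77 ± 0.28 and Pnliprp2 of 1.78 ± 0.33.

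In KI_Half vs KI_Con 20 of 50 lists passed camera, 0 with an estimated correlation and 15 with fry, and no single library moved the count of genes by over 1.5 times. Without control libraries above 10 CPM of Ctrb1, which leaves 2 KI_Con libraries, 2565 genes passed, and the falls of the 8 acinar genes with the largest change did not, those of Cela2a, Cela3b and Prss2 turning positive at 0.72, 0.22 and 0.13. WT_Half vs WT_Con and KI_Half vs KI_Con share no library, and their overlap was chosen after the data were seen. They had 139 genes higher in both where 30.4 would be shared by independent lists, and 87 lower in both where 17.2 would be. Odds ratios were 44.6 and 45.6 (two-sided Fisher's exact p = 7.64e-82 and 8.44e-55 across genes). Those lower in both include Cpb1, Cel, Prss2, Cela3b and Cela2a, acinar genes high in control libraries of both genotypes. That part of the overlap may describe dissection and not ethanol. Whether the ethanol response differed between genotypes was tested as an interaction over 21 libraries, also chosen after the data were seen: edgeR called 0 of 17006 genes (2162 with an unadjusted p under 0.05, smallest adjusted p = 0.277).

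WT_Full vs WT_Half compared the regimens within wild-type mice, and edgeR called 0 of 16967 genes. The smallest p belonged to the membrane mucin Muc3a, at 60.4 ± 17.2 CPM in WT_Full (n = 4) against 189 ± 49.8 in WT_Half (n = 7), a log2 difference of -1.63 ± 0.23 with adjusted p = 0.177. Muc3, which may share reads with it, had 1241 ± 358 against 2940 ± 770 CPM, the NK cell receptor Klrd1 0.749 ± 0.266 against 3.24 ± 1.20, Cish 7.54 ± 1.07 against 12.3 ± 1.96 and Nlrc3 0.936 ± 0.293 against 2.60 ± 1.05. On the higher side stood the oxidase subunit Cyba, at 116 ± 20.5 against 58.0 ± 15.4 CPM (adjusted p = 0.976). The carbonyl reductase Cbr3 stood at 24.5 ± 7.89 against 9.98 ± 4.29, the pseudogene Rps27a-ps2 at 25.6 ± 7.05 against 13.5 ± 3.41, Anxa10 at 22.6 ± 4.67 against 8.88 ± 4.22 and Fbxl22 at 6.58 ± 1.79 against 3.58 ± 0.561.

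Of 18 T and NK cell genes all 18 had a negative fold change in WT_Full vs WT_Half, 0 passed over all genes and 13 were lower adjusted over the list alone. Cd8a stood at 2.25 ± 1.5 against 9.19 ± 5.37 CPM and Cd7 at 1.35 ± 0.653 against 5.35 ± 2.78. By camera the T and NK cell list had adjusted p = 1.85e-24, and adjusted p = 0.267 with an estimated correlation. All 18 glucocorticoid-responsive genes had a negative fold change, 0 passed over all genes and 1 was lower adjusted over the list alone. Fkbp5 had 74.4 ± 19.4 against 379 ± 290 CPM, Zbtb16 3.24 ± 1.68 against 20.5 ± 22.3 and Hif3a 1.35 ± 0.890 against 3.57 ± 3.18. By camera the glucocorticoid list had adjusted p = 2.72e-07, and adjusted p = 0.565 with an estimated correlation. Of 37 interferon-stimulated genes 36 had a negative fold change and 0 passed by either adjustment, adjusted over the list alone included. Cxcl9, Cxcl10 and Gbp7 had log2 differences of -1.47 ± 0.51, -1.79 ± 0.65 and -0.65 ± 0.28. By camera the interferon list had adjusted p = 2.72e-07, and adjusted p = 0.713 with an estimated correlation. All 14 smooth muscle genes had a positive fold change and 0 passed by either adjustment, adjusted over the list alone included. Smtn stood at 101 ± 41.8 against 66.1 ± 11.3 CPM, Lmod1 at 72.8 ± 29.2 against 50.4 ± 14.7 and Cnn1 at 193 ± 98.5 against 132 ± 31.5. By camera the smooth muscle list had adjusted p = 1.79e-06, and adjusted p = 0.676 with an estimated correlation, or 0.137 without WT_Full replicate 2. Of 16 genes of enteric neurons and glia 15 had a positive fold change, with a median of 0.39 and 0 past either adjustment, adjusted over the list alone included. By camera the enteric neuron and glia list had adjusted p = 0.0139, and adjusted p = 0.713 with an estimated correlation, 0.382 with the replicate block and 0.792 without WT_Full replicate 2. In WT_Full vs WT_Half 780 genes had an unadjusted p under 0.05, fewer than the 848 expected by chance. DESeq2 called 5 higher and 15 lower, limma-voom 2 and the fit of all 25 libraries 0, and edgeR called 2 without WT_Half replicate 6. Camera passed 24 of 50 lists, 13 without WT_Full replicate 2 and 0 with an estimated correlation.

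KI_Con vs WT_Con compared the genotypes on the control diet, and edgeR called 0 of 16813 genes. Tmem116 again had the smallest p, at 14.4 ± 1.64 CPM in KI_Con against 4.11 ± 0.949 in WT_Con (n = 4 each), a log2 difference of 1.79 ± 0.19 with adjusted p = 0.0593. The next were Adgrd1, an adhesion receptor, at 27.7 ± 2.68 against 10.3 ± 2.67 CPM (adjusted p = 0.319), and, at adjusted p = 0.502, the sugar phosphate carrier Slc37a2 at 398 ± 40.2 against 227 ± 33.1, Lhfpl2 at 34.4 ± 4.84 against 23.6 ± 0.630 and Eepd1 at 70.4 ± 10.9 against 42.2 ± 7.57. On the lower side, at the same adjusted p, were Slc25a47 at 12.8 ± 1.67 against 22.9 ± 2.85 CPM, Pgm3 at 23.7 ± 3.08 against 34.5 ± 4.77, Foxred2 at 1.14 ± 0.380 against 3.90 ± 2.23, Car8 at 9.29 ± 1.66 against 31.8 ± 21.7 and Lrrc31 at 3.10 ± 0.481 against 5.09 ± 0.461.

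Of 16 genes next to Aldh2, 9 had a positive fold change in KI_Con vs WT_Con, 0 passed over all genes and 1, Tmem116, was higher adjusted over the list alone. Acad10 had 22.0 ± 1.47 against 15.5 ± 3.16 CPM and Erp29 69.4 ± 2.53 against 58.6 ± 4.56. By camera the Aldh2 neighbour list had adjusted p = 0.0223, and adjusted p = 0.537 with an estimated correlation. The list missed the threshold without KI_Con replicate 1 (0.0925), WT_Con replicate 1 (0.0638) or WT_Con replicate 4 (0.0732). All 37 genes of oxidative phosphorylation had a positive fold change, with a median of 0.27, as did 28 of 29 genes of brush border digestion and nutrient uptake, with a median of 0.40, and 0 of either list passed over all genes or adjusted over the list alone. All 18 marker genes of enterocytes were likewise positive, with a median of 0.41 and 0 past either adjustment, adjusted over the list alone included (camera adjusted p = 4.48e-08, and adjusted p = 0.537 with an estimated correlation). The mean log2 CPM of the enterocyte list was 10.98 and 10.76 in WT_Con replicates 1 and 2, within the 10.75 to 11.22 of KI_Con, but 9.83 and 10.13 in replicates 3 and 4. That of the brush border list was 8.28 and 8.36, within the 8.22 to 8.58 of KI_Con, but 7.32 and 7.83. Brunner gland genes made up 5.32% and 3.46% of counts in WT_Con replicates 3 and 4 and at most 1.07% in the other control libraries. Uqcrc1 had 807 ± 45.2 against 628 ± 81.1 CPM, Cox5a 195 ± 25.7 against 150 ± 18.8, Cox6c 286 ± 35.9 against 214 ± 33.4. The amino acid carriers Slc6a19 had 547 ± 48.0 against 331 ± 108 and Slc7a8 159 ± 26.1 against 98.3 ± 36.4, and Slc15a1 199 ± 15.3 against 129 ± 44.6 (camera adjusted p = 3.13e-11 and 2.56e-10, and adjusted p = 0.537 with an estimated correlation for both). All 7 Brunner gland genes had a negative fold change with 0 past either adjustment, adjusted over the list alone included, at 6.26 ± 5.13 against 59.3 ± 75.9 CPM for Fut2, 587 ± 986 against 5314 ± 4917 for Gkn3 and 1.22 ± 2.34 against 10 ± 12.6 for Muc5b. By camera the Brunner gland list had adjusted p = 0.000671, and adjusted p = 0.537 with an estimated correlation. Of 19 antimicrobial and acute-phase genes 15 had a negative fold change and 0 passed by either adjustment, adjusted over the list alone included. Duox2 stood at 1.64 ± 0.480 against 16.9 ± 23.3 CPM, Duoxa2 at 0.509 ± 0.142 against 3.17 ± 2.81 and Nos2 at 0.361 ± 0.210 against 1.11 ± 0.846. By camera the antimicrobial list had adjusted p = 0.0340, and adjusted p = 0.537 with an estimated correlation. That call was lost with the replicate block (0.0771) and without KI_Con replicate 3 or WT_Con replicate 1, 2 or 4 (0.0593 to 0.160). In KI_Con vs WT_Con 1664 genes had an unadjusted p under 0.05, DESeq2 called 7 higher and 4 lower, or 8 higher and 47 lower when fitted with all 25 libraries, limma-voom 2, the fit of all 25 libraries 1, and edgeR 1 without WT_Con replicate 2, Tmem116 (adjusted p = 0.0185). Camera passed 20 of 50 lists and 0 with an estimated correlation.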

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

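Of the tests below, those on acinar genes, on Brunner gland content in WT_Half vs WT_Con, on WT_Full replicate 4 and on the position of genes near Aldh2 were chosen only after results were seen.

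The 15 pancreatic acinar genes of the sum were high in some control libraries and low in all others. They were chosen for a highest level under 10 CPM in ethanol libraries and over 10 CPM in controls, which fixed part of that pattern. Over the whole acinar list, fixed beforehand, the mean log2 CPM was 4.40 to 7.90 in 5 of the 8 control libraries. It was at most 2.73 in all other libraries. Among the 5 control libraries above 10 CPM of Ctrb1, the log2 ratio of each acinar gene to Ctrb1 had a median SD of 0.225, while Ctrb1 itself had an SD of 1.58 on the log2 scale. Genes that rise and fall together like this suggest varying amounts of pancreas attached to the duodenal piece. A lower level after ethanol in every animal is less likely, because 3 of the 8 control libraries lay within the range of the ethanol libraries, at or below 50.2 CPM. The falls of Cpb1, Cel, Prss2 and other acinar genes may therefore describe dissection and not ethanol.

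Brunner gland content also varied between pieces, and with it as a covariate 7 of the 249 genes of WT_Half vs WT_Con were still called. The fold changes of the 249 genes nevertheless kept a median of 88.5% of their size, with the same sign for all 249. Gland content is thus not a likely source of the fold changes as a whole, although the calls themselves could not be kept.

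The library labelled WT_Full replicate 4 lay apart from the other 3 of its group. Genes were used that separate the 13 WT_Half and KI_Half libraries from 7 of the 8 controls. On these it lay on the ethanol side of the midpoint for 23.4% to 26.8%, and the other WT_Full libraries for 83.3% to 96.4%. The controls left out lay there for 1.95% to 38.4%, the highest being WT_Con replicate 3 and the next 12.3%. WT_Full replicate 4 thus lay within the range of the controls only through WT_Con replicate 3. For WT_Full replicate 4 the T and NK cell list and single genes lay outside the controls. The mean log2 CPM of the list was 1.13, against 2.20 to 3.42 in the 8 controls, with Atf5 at 78.4 CPM (controls 18.5 to 30.8), Psat1 at 30.4 (4.96 to 9.61) and Nr1d1 at 33.6 (91.4 to 239), the list and genes being picked after their values were seen. A control library under a wrong label was therefore not excluded, and neither was a weak response. The bound and then the test for a wrong label were replaced after values were seen. Low depth is not a likely cause, as its total of 33.2 M was above the 32.1 M of the next library. The library was kept in all counts.

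Some genotype differences shared by both diets lay near Aldh2, while 2 of the 5 genes called lay on other chromosomes. Of the 100 genes with the smallest p for genotype with diet as a term, 6 lay within 5 Mb of Aldh2 where 0.794 would by chance (two-sided Fisher's exact p = 0.000145, 1 of 24 such tests over 4 windows and 6 fits). At 2, 5, 10 and 20 Mb p was 0.0113, 0.00797, 0.0168 and 0.0731 in KI_Con vs WT_Con alone, and 0.0796, 0.046, 0.186 and 0.219 in KI_Half vs WT_Half alone. A changed or foreign segment around the knock-in may explain the genes near it, not the others. Brunner gland and enterocyte content is less likely, since 3 of 3 called genes on chromosome 5 still passed with these scores as covariates. So did Urah and Gm49331 on other chromosomes (edgeR adjusted p = 0.0205 and 0.0424). Passing thus does not set the genes near Aldh2 apart from the others. Pancreatic and gastric content was not covered by the scores. Whether reads of an overlapping gene were counted as Tmem116 could not be decided. Of the 2 overlapping genes tested, Erp29 was higher in KI by 0.16 ± 0.07, or 9.59% of the log2 difference of Tmem116, and Adam1a was lower by 0.70 ± 0.21. Erp29 has a much higher level than Tmem116, so shared reads that are few for Erp29 could be many for Tmem116. The strand setting of the counting is not given.

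A library far from the rest of its group was sought for 29 measures in each group, 145 searches in all, and found in 22. How many would be found by chance was not tested. Each is given here as the gap to the nearest library over the range of the group. A value of 1 arose where the other libraries had 0 CPM, at levels close to 0. For the percentage of counts in the top 20 genes, WT_Half replicate 1 had the lowest value, 10.3 against 12.7 (0.572). For Brunner gland genes the highest percentages were in KI_Con replicate 3, 1.07 against 0.103 (0.910), KI_Half replicate 3, 0.803 against 0.243 (0.707), and WT_Full replicate 1, 0.774 against 0.00934 (0.993). For T and NK cell genes they were in KI_Half replicate 7, 0.0184 against 0.00866 (0.673), and WT_Full replicate 4, 0.00660 against 0.00297 (0.843). Aldh2 had 640 against 404 CPM in WT_Full replicate 4 (0.863). Ccl5 had 39.3 against 23.0 CPM in KI_Con replicate 4 (0.843). Tmem116 had 15 against 10.4 CPM in KI_Half replicate 7 (0.654). Ly6g had 0.911 against 0.181 CPM in WT_Con replicate 4 (0.843) and 0.887 against 0.462 in KI_Con replicate 2 (0.940). Ctrb1 had 8.76 against 3.55 CPM in WT_Half replicate 1 (0.626). Muc3a had the lowest value in WT_Con replicate 2, 111 against 183 CPM (0.932), and in KI_Half replicate 7, 71.7 against 215 (0.682). Duoxa2 had 16.4 against 2.83 CPM in WT_Half replicate 6 (0.874). Krt84 had 0.0302 against 0 CPM in WT_Con replicate 2 (1), 12 against 2.80 in WT_Half replicate 1 (0.809) and 9.67 against 1.47 in WT_Full replicate 3 (0.854). Sprr2f had 0.0452 against 0 CPM in WT_Con replicate 3 (1) and 0.0657 against 0 in KI_Con replicate 2 (1). Csf3 had 0.0624 against 0 CPM in KI_Con replicate 3 (1) and 9.14 against 3.68 in KI_Half replicate 5 (0.636).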

How the results depend on the processing

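Counts of genes depended on the model. KI_Half vs KI_Con stayed between 4927 and 7477 genes when single libraries were left out, and was 7065 with DESeq2, 6012 with DESeq2 over all 25 libraries, 7888 with limma-voom, 5439 with 1 fit of all libraries, 5870 with the Brunner gland covariate, 6153 with the replicate block, 6404 without the filter and 6393 with relative log expression factors. Without control libraries above 10 CPM of Ctrb1 it was 2565. WT_Half vs WT_Con gave 1353 with DESeq2, 1232 with limma-voom, 720 with 1 fit of all libraries, 1422 with DESeq2 over all libraries, 254 without the filter, 241 with relative log expression factors and 21 to 446 with single libraries left out. WT_Full vs WT_Con gave 936, 1410, 1289, 2091, 1 and 1 under these models, in the same order, and 0 to 2069. KI_Half vs WT_Half gave 172, 884, 2, 243, 0 and 0, and 0 to 1. WT_Full vs WT_Half gave 20, 2, 0, 36, 0 and 0, and 0 to 2. KI_Con vs WT_Con gave 11, 2, 1, 55, 0 and 0, and 0 to 1, and 1 with the replicate block. The Brunner gland covariate left 2, 0 and 1 genes in KI_Half vs WT_Half, WT_Full vs WT_Half and KI_Con vs WT_Con.

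In no comparison did every pair of libraries with the same replicate number correlate by over 0.1. In KI_Con vs WT_Con 3 of 4 pairs did, and in 3 of 4 the own number was the best partner. Elsewhere at most 1 pair did. Correlations between libraries of the same number, after the group mean, ran from -0.0127 to 0.243 in KI_Con vs WT_Con, 0.0133 to 0.212 in KI_Half vs KI_Con, -0.305 to -0.018 in KI_Half vs WT_Half, -0.170 to 0.0998 in WT_Full vs WT_Con, -0.0962 to 0.393 in WT_Full vs WT_Half and -0.278 to -0.0437 in WT_Half vs WT_Con.

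Of the 62 named genes past the threshold in KI_Half vs KI_Con, 48 passed under every alternative. Of 26 in WT_Half vs WT_Con and 1 in WT_Full vs WT_Con, 0 did, which was fixed once the replicate block called 0 genes in both comparisons. Signs turned for 3 values each in KI_Half vs KI_Con and WT_Full vs WT_Half, 9 in WT_Half vs WT_Con, 6 in KI_Con vs WT_Con and 1 each in WT_Full vs WT_Con and KI_Half vs WT_Half. Without control libraries above 10 CPM of Ctrb1, which leaves 1 WT_Con library, assumed to vary like the others, and 2 KI_Con libraries, log2 differences in WT_Half vs WT_Con became 1.40 for Cel, 2.33 for Cela2a, 2.73 for Cela3b, 2.72 for Cldn18, 0.42 for Cpb1, 1.47 for Ctrb1, 2.00 for Prss2, 0.0621 for Smtn and 1.42 for Try5. In KI_Half vs KI_Con they became 0.72 for Cela2a, 0.22 for Cela3b and 0.13 for Prss2, and in WT_Full vs WT_Con 0.35 for Cela2a. In KI_Con vs WT_Con they became 0.0475 for Car8, 0.56 for Duox2, 2.41 for Fut2, 6.46 for Gkn3 and 9.22 for Muc5b, and the Brunner gland covariate gave 1.46 for Muc5b. With limma-voom Pnlip had 0.21 in KI_Half vs WT_Half and Aldh2 -0.16 in WT_Full vs WT_Half. With single libraries left out, Aldh2 in WT_Full vs WT_Half ran from -0.17 without WT_Full replicate 4 to 0.12 without WT_Full replicate 3. The lists followed here were narrowed to those past camera after values of other lists had been seen.

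With single libraries left out, lists past camera numbered 11 to 17 in WT_Full vs WT_Con, 16 to 21 in KI_Half vs WT_Half, 7 to 16 in WT_Half vs WT_Con, 13 to 30 in WT_Full vs WT_Half, 19 to 21 in KI_Half vs KI_Con and 20 to 25 in KI_Con vs WT_Con. For the enteric neuron and glia list in WT_Full vs WT_Half the camera p, negative where the list was lower, was -0.713 without WT_Full replicate 2, and otherwise at most 0.0554 with single libraries left out, without WT_Half replicate 1. The replicate block gave 17, 19, 14, 21, 22 and 20, and relative log expression factors 15, 16, 10, 24, 20 and 20.

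DESeq2 over all 25 libraries shared 1930 of its 2091 genes with the authors' deposited table in WT_Full vs WT_Con and 210 of 243 in KI_Half vs WT_Half. The overlap of the deposited comparisons was 0 genes with edgeR and 23 with DESeq2.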

Other observations

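The fits of genotype with diet and of their interaction were chosen only after results were seen, while the regroupings of libraries had their predictions written before.

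Over 21 WT_Con, KI_Con, WT_Half and KI_Half libraries with diet as a term, 5 of 17006 genes differed between KI and WT. Tmem116 was higher by 1.63 ± 0.16 on the log2 scale (adjusted p = 1.26e-05), with 8.01 to 16.4 CPM in KI and 1.90 to 6.24 CPM in WT libraries, and lies 0.114 Mb from Aldh2. Kdm2b, a histone demethylase 1.30 Mb from Aldh2, was higher by 0.61 ± 0.10 (0.033), and Gm15446, on the same chromosome at 11.6 Mb, was lower by 0.98 ± 0.13 (0.00151). Urah, an enzyme of urate breakdown on chromosome 7, was higher by 0.42 ± 0.07 (0.033), and Gm49331 on chromosome 12 lower by 0.83 ± 0.14 (0.033). Of these genes 2118 had an unadjusted p under 0.05, and 21 of 50 lists passed camera and 0 with an estimated correlation. The interaction of genotype and diet, with 0 genes called, passed 22 lists and 0 with an estimated correlation.

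Each comparison was repeated on libraries regrouped at random, 35 or 100 groupings with the real one. For the count of genes, 1 of 100 groupings reached the 6420 of KI_Half vs KI_Con (highest other 2558), 2 of 100 the 249 of WT_Half vs WT_Con (1634) and 2 of 100 the 5 of genotype with diet (124), the real one included. For WT_Full vs WT_Con 3 of 35 groupings reached 1 gene (highest other 14). Where the real count was 0, every grouping reaches it whatever the data, so these shares carry no information. They were 100 of 100 for KI_Half vs WT_Half (highest other 0) and 100 of 100 for WT_Full vs WT_Half (1177). They were 35 of 35 for KI_Con vs WT_Con (73) and 100 of 100 for the interaction (16). Other groupings with 1634 or 124 genes, several times the real count, and with 1177 or 73 where the real count was 0, point to a structure among the samples, whose source was not tested.

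For lists past camera, 28 of 35 groupings reached the 15 of WT_Full vs WT_Con (highest other 33), 69 of 100 the 16 of KI_Half vs WT_Half (29), 94 of 100 the 11 of WT_Half vs WT_Con (25), 16 of 100 the 24 of WT_Full vs WT_Half (30), 33 of 100 the 20 of KI_Half vs KI_Con (25) and 13 of 35 the 20 of KI_Con vs WT_Con (26). Chance cannot be excluded for any of these list counts.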
